A study of Homo sapiens with 6 samples.

How the data were processed

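The samples were 6 libraries of the TC-71 cell line, 3 wildtype and 3 with XG knockout, grouped and numbered by their titles. Per the labels' protocols, libraries were made with a stranded mRNA kit. Per the submitters' processing notes, reads were processed with bcl2fastq and STAR 2.7.6a on GRCh38. The deposited counts are whole-number fragment counts per gene, made by the authors with featureCounts of Subread 2.0.1 on exons of GENCODE 33 genes with reverse-strand, paired-end settings, per the file headers. Per the file headers no option for multi-mapping reads was set, so fragments mapping to several places or several genes were left out, which lowers counts of near-identical genes. Strand-specific counting keeps a gene apart from its antisense partner. The authors also deposited log2 fold changes and their standard errors from a comparison that the submitters' processing notes attribute to DESeq2 1.38.3 in R 4.2.2. The authors' deposited p-values in that table include adjusted values, with none for genes left out by independent filtering. The direction of the deposited log2 fold changes is not stated and was checked against the counts. All count columns were matched to samples by name. The 45 entries for chromosome Y copies of pseudoautosomal genes held 0 counts.

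Total counts per library ranged from 22557187 to 31214099. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 14425 genes with 99.92% of counts. Counts were scaled by trimmed mean of M values (TMM) and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, two-sided, no covariates) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Standard errors were obtained from the fold change and the F statistic. Values in CPM are counts scaled to TMM-adjusted library sizes, and errors beside them are SDs of 3 libraries. Gene positions, names and types are those of the count table. Replicates of a group differed by more than sampling noise in every pair (chi-square per gene 1.46 to 4.70). Knockout replicate 3 was closer to the wildtype libraries (2.15 to 2.38) than to knockout replicates 1 and 2 (4.70 and 4.33).

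A total of 39 gene lists were fixed before the data were examined, and all 1025 entries matched a row; 37 lists had at least 5 tested genes. Lists and 23 chromosomes were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, and again with an estimated correlation, with which 0 lists were called and 4 had an unadjusted p under 0.05. The self-contained test fry called 3 lists, all lower: G1/S and DNA replication, XG neighbours and blood group genes, the last 2 with XG among their members. Rank-based camera called 2. At an unadjusted p under 0.05, 2422 genes passed in edgeR. The named genes follow a rule fixed before the data were examined. They are XG and tested members of its neighbour list; among protein-coding genes past the threshold with at least 5 CPM in the higher group and no overlap of groups, the 10 with the largest positive and the 10 with the largest negative fold change, and the 5 up and 5 down with the largest CPM difference; and up to 4 called members per list by smallest p, or, in a list with none called, up to 2 members by smallest p as values. Genes named outside it are marked as chosen after their values were seen.

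Alternatives fixed in advance were other scalings (relative log expression, upper quartile), DESeq2 1.42.0, limma voom, no filter on low counts, a stricter filter (at least 100 counts in 3 libraries), the replicate number as a block, leaving out each library, an adjusted p of 0.01, and other set tests. Alternatives chosen after seeing the data were a correction for GC content, for length and for both, knockout replicate 3 alone, GC correction with each library left out (for counts of genes), and GC correction with an estimated correlation. With 1 knockout library the spread comes from the wildtype libraries alone, and the lone library is assumed to vary like them. The GC correction removed from each library a lowess trend (span 0.5) of log2 CPM, less each gene's mean over libraries, on the GC content of the longest transcript, taken from GENCODE transcripts of an earlier release by gene identifier; 99.54% of tested and 100% of called genes had a value.

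The scripts were tested on simulated data for the comparison of XG knockout against wildtype with 14425 genes. Of 50 genes changed at each size, 18% were recovered at 1.1-fold, 42% at 1.2-fold, 80% at 1.5-fold and 96% at 2-fold, and 10 of 128 calls (7.81%) were false. A simulated GC trend gave 44 false calls without and 6 with the correction.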

Results

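Gene expression was measured by stranded, paired-end mRNA sequencing in TC-71, an established human Ewing sarcoma cell line, with and without knockout of XG. XG encodes a cell-surface glycoprotein that carries the Xg blood group antigen. The gene lies on chromosome X beside CD99, the membrane protein used as a diagnostic marker of Ewing sarcoma. Each group had 3 libraries, and the 6 libraries formed 1 comparison, which asked how the transcriptome of the line differs when XG is knocked out. The deposited counts summed to 27765294, 26307681 and 22557187 fragments in wildtype replicates 1, 2 and 3, and to 24934343, 31214099 and 28908403 in knockout replicates 1, 2 and 3. Of 60662 genes in the table, 27252 had a count in at least 1 library and 14425 were tested. At this depth the common biological coefficient of variation was 3.28% and the median standard error (SE) of a log2 fold change was 0.0636. Nothing in the labels says whether the replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

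XG was reduced but still present in every knockout library. XG (ENSG00000124343.13, chromosome X, 2752048 to 2816500, plus strand, GRCh38) had 1254, 1228 and 999 counts in the wildtype libraries and 746, 948 and 836 in the knockout libraries. This corresponded to 45.7 ± 1.37 CPM (counts scaled to library size; SD, n = 3) in wildtype and 29.6 ± 0.64 CPM (SD, n = 3) in knockout cells. The knockout level was 64.8% of wildtype, a log2 fold change of -0.63 (SE 0.0478; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.65e-06). All 3 knockout libraries lay below all 3 wildtype libraries, in the direction of the labels. A count summed over the exons of a gene does not show whether the remaining transcript encodes an intact protein. The labels do not say whether the knockout cells were a pool or a single clone, so the XG level may be that of a mixture, and differences between clones cannot be told from those of the knockout.

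Among 8 tested members of the list of XG neighbours and relatives, XG and CD99 fell and 6 did not pass the test (2 lower also when adjusted over the list alone). CD99 went from 496 ± 7.76 to 458 ± 2.64 CPM (SD, n = 3), a log2 fold change of -0.12 (SE 0.0253, edgeR adjusted p = 0.0302). Its transcript has a GC content of 56.5%, and knockout replicates 1 and 2 were lower for GC-rich genes in general, as described at the end. With a GC correction chosen after seeing the data, the CD99 log2 fold change was -0.068 (SE 0.024, edgeR adjusted p = 0.142), and the call was also lost without wildtype replicate 1 (adjusted p = 0.201), 2 (0.191) or 3 (0.115) and without knockout replicate 2 (0.0787). With knockout replicate 3 alone the log2 fold change was -0.12 (edgeR adjusted p = 0.00119), in a fit where the wildtype libraries alone supply the spread and the lone knockout library is assumed to vary like them. Over the alternatives its adjusted p ranged from 0.00119 to 0.201. GYG2, the glycogenin gene next to XG, was at 145 ± 2.33 CPM in wildtype and 144 ± 2.33 CPM in knockout cells (SD, n = 3). PRKX, NLGN4X, ZBED1, DHRSX and the CD99 paralog CD99L2 had log2 fold changes of 0.036, 0.0095, -0.067, -0.14 and 0.034, none past the test. The camera set test called the list lower (adjusted p = 0.000913), with XG itself among its members, and adjusted p = 0.265 with an estimated correlation.

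**Figure D1:**
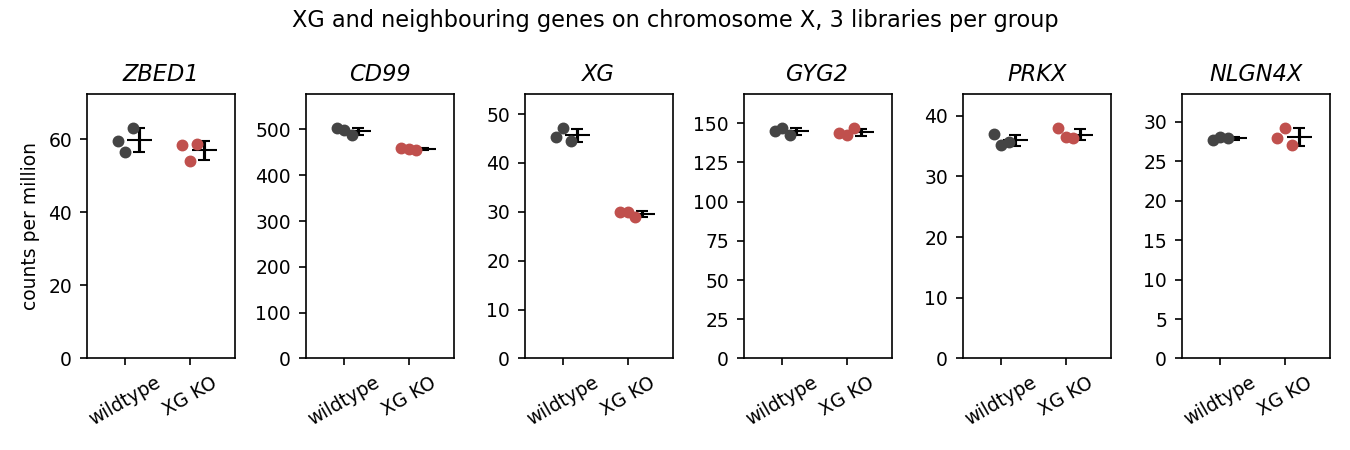
Expression (CPM) of XG and 5 neighbouring genes on chromosome X in the 3 wildtype (grey) and 3 knockout (red) libraries, each axis starting at 0; points are libraries, and black bars show the mean and SD (n = 3). XG fell from a mean of 45.7 to 29.6, while GYG2 stood at 145 and 144.

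Differences across the transcriptome were many and small. At an edgeR adjusted p under 0.05, 196 genes changed, 64 higher and 132 lower in knockout cells, and 193 of them were protein-coding. The median absolute log2 fold change of the called genes was 0.238. A change of at least 1.5-fold was seen in 15 genes and of at least 2-fold in 6, all of the latter at low expression. These were ANO1, RAPGEF5 and EPB41L3, at log2 fold changes of 1.47, 1.47 and 1.53, and HOXA7, MEG3 and CTSZ, at -1.11, -1.01 and -1.005. Of these, ANO1, RAPGEF5, EPB41L3 and MEG3 were named after their values were seen. The 3 libraries of a group did not overlap those of the other in 195 of the 196 genes, and in 20.5% of all genes tested, against 10% by chance. After GC correction 339 genes passed, 157 higher and 182 lower, so that lower genes made up 53.7% of calls against 67.3% before. Of the 196 genes, 158 were called again with the same sign. The count depended on single libraries: 24, 26 and 18 genes passed without wildtype replicate 1, 2 or 3, 67 and 41 without knockout replicate 1 or 2, and 1851 without knockout replicate 3. With GC correction 386 genes passed without knockout replicate 3. Of 54 called genes selected by the naming rule, 42, 40 and 44 lost their call without wildtype replicate 1, 2 or 3, 25 and 36 without knockout replicate 1 or 2, and 23 with knockout replicate 3 alone. XG, SLC7A2, PRRX2, DACT2, BEX1, TRIM28, ALDH1L2 and ATF5 were among the genes past the threshold in each alternative run for them. Of these, TRIM28 and ATF5 lie on chromosome 19, whose genes were lower as a set, as described at the end. TRIM28 lies within the distal 19q block given there, so its fall may belong to that regional shift.

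Among called protein-coding genes with at least 5 CPM in the higher group and no overlap of groups, the largest increases included CNTNAP2, SLC7A2, IL2RB, APOE and CHAC1. Some of these genes lay near that floor. CNTNAP2, a neurexin family adhesion protein, rose from 9.51 ± 0.828 to 13.8 ± 0.584 CPM (SD, n = 3; log2 fold change 0.54, SE 0.0809). SLC7A2, a cationic amino acid transporter, rose from 31.5 ± 0.268 to 44.8 ± 0.787 CPM (log2 fold change 0.51, SE 0.0459, edgeR adjusted p = 1.36e-05). IL2RB, the interleukin 2 receptor beta chain, and APOE, the lipid carrier apolipoprotein E, had log2 fold changes of 0.46 and 0.44. CDC42EP3, TLL1, TBC1D8B and SDC3 followed at 0.40, 0.39, 0.38 and 0.38. By absolute level the largest increases were in TPT1, from 1691 to 1824 CPM, and in IVNS1ABP, MIB1, IL1RAP and RNF141, which rose to 110.4%, 109.3%, 111.5% and 113.3% of wildtype. After GC correction all of these genes were called again.

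Under the same conditions, with at least 5 CPM in the higher group, the largest decreases were in HR, ADD2, PRRX2, XG and DACT2. HR and ADD2 lay near that floor, ADD2 at 7.20 CPM in wildtype and 4.59 CPM in knockout cells. HR, a histone demethylase and nuclear receptor corepressor, went from 7.57 ± 0.805 to 4.17 ± 1.31 CPM (SD, n = 3; log2 fold change -0.85, SE 0.155). ADD2, a membrane skeleton protein, and PRRX2, a homeobox transcription factor of mesenchyme, had log2 fold changes of -0.66 and -0.65. DACT2, a regulator of WNT and TGF-beta signalling, stood at 68.3% of wildtype (edgeR adjusted p = 0.000694). SAMD11, BEX1, RAX, PDLIM1 and JUNB had log2 fold changes of -0.47, -0.46, -0.42, -0.38 and -0.37. By absolute level the largest decreases included those of FTL, the ferritin light chain, from 1669 to 1473 CPM, TRIM28, a corepressor, from 859 to 744 CPM, and SLC25A6 and RPL18. SLC25A6, with a GC content of 64.89%, stood at 578, 570 and 691 CPM in knockout replicates 1, 2 and 3. Its lowest wildtype library was at 693 CPM, so knockout replicate 3 lay close to wildtype. The SLC25A6 log2 fold change of -0.21 became -0.097 after GC correction, still called. Called lower genes had a median GC content of 58.96%, against 44.04% for called higher genes and 48% for all genes tested, and the folds of GC-rich genes shrank with GC correction: TRIM28 from -0.21 to -0.099 and SAMD11 from -0.47 to -0.34, both still called. HR stayed past the threshold after GC correction (log2 fold change -0.73, adjusted p = 0.0004) and lost its call without wildtype replicate 1 (0.105) or 3 (0.111) or knockout replicate 2 (0.0643). With knockout replicate 3 alone, where the wildtype libraries supply the spread, the HR log2 fold change was -0.43 (adjusted p = 0.163).

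**Figure D2:**
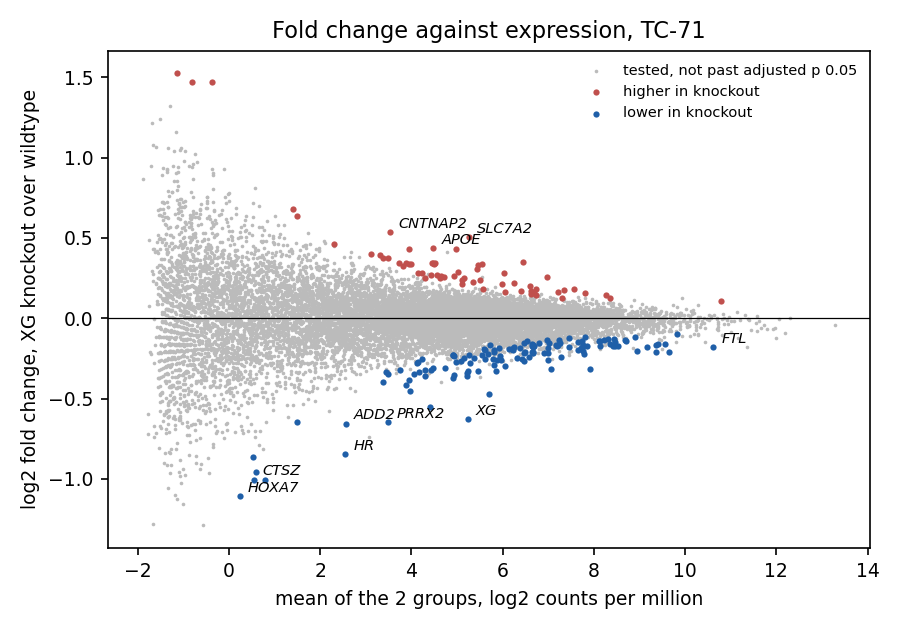
Log2 fold change of XG knockout over wildtype (vertical axis) against mean expression in log2 CPM (horizontal axis) for the 14425 genes tested; red and blue points are the 64 genes higher and 132 genes lower at an edgeR adjusted p under 0.05, and grey points are the others. Most called genes lie within a log2 fold change of 1 of 0, and the 6 outside it are at low expression.

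Targets of the amino acid response, which the transcription factor ATF4 activates when amino acids are scarce, were called higher as a set at camera's preset correlation and not with an estimated correlation (adjusted p = 0.265), and 27 of 32 members did not pass on their own. Among the 32 tested genes, 28 had a positive fold change; 4 were called higher and 1 lower over all genes, and 9 higher and 1 lower adjusted over the list alone. CHAC1, a glutathione-degrading enzyme, rose from 13.2 ± 0.224 to 17.8 ± 1.51 CPM (SD, n = 3; log2 fold change 0.43). ALDH1L2, a mitochondrial folate enzyme, rose from 115 ± 1.89 to 137 ± 2.16 CPM (log2 fold change 0.26, edgeR adjusted p = 0.000491). SESN2, an inhibitor of mTORC1 signalling, and DDIT4, another such inhibitor, which is named as the fifth called member after its values were seen, each rose by 0.34 on the log2 scale. ATF5, a transcription factor related to ATF4 and encoded on chromosome 19, fell by 0.26 (SE 0.0367). The list amino acid response (ATF4) had a median log2 fold change of 0.056 and was called higher by camera at the preset correlation (adjusted p = 1.4e-06), and not by fry (adjusted p = 0.0798). After GC correction its median was 0.0698 and camera's adjusted p = 4.78e-16, with adjusted p = 0.0665 with an estimated correlation; over the alternatives it ranged from 4.78e-16 to 0.265.

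Genes of the p53 response had a median log2 fold change of 0.0525, with 15 of 23 positive. CDKN1A, the cyclin-dependent kinase inhibitor p21, rose to 25.2 ± 0.511 CPM (SD, n = 3), 126.2% of wildtype (log2 fold change 0.34, edgeR adjusted p = 0.00772), and SESN2, also counted above, was the other called member. Adjusted over the list alone, 5 were higher and 3 lower. Camera called the p53 targets higher (adjusted p = 0.0411; adjusted p = 0.672 with an estimated correlation), and the call was lost without wildtype replicate 2 (adjusted p = 0.119), wildtype replicate 3 (adjusted p = 0.134) or knockout replicate 3 (adjusted p = 0.154). After GC correction the p53 targets had adjusted p = 0.00723, the lowest over the alternatives, and the highest was 0.672.

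Genes of G1/S and DNA replication were called lower as a set at camera's preset correlation (adjusted p = 0.000913) and not with an estimated correlation (adjusted p = 0.265). Without GC correction fry also called the list lower (adjusted p = 0.0418), and 1 of 32 members passed on its own. A negative fold change was seen in 26 of 32, with a median log2 fold change of -0.0545. UNG, which removes uracil from DNA, was the member called over all genes, from 183 ± 0.679 to 168 ± 0.762 CPM (SD, n = 3), and 8 were lower adjusted over the list alone. In the alternatives camera's adjusted p for the G1/S and DNA replication list ranged from 5.66e-05 to 0.328. The G2/M and mitosis list was not called (adjusted p = 0.489), and its called member CDC20 had a log2 fold change of -0.13, which became -0.067 and lost its call after GC correction.

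Antigen presentation genes were called lower as a set at camera's preset correlation (adjusted p = 0.00318) and not with an estimated correlation (adjusted p = 0.415). Of 10 tested, 8 were negative, and the median log2 fold change was -0.146. TAP2, a subunit of the peptide transporter, fell from 1.86 ± 0.134 to 1.02 ± 0.137 CPM (SD, n = 3; log2 fold change -0.86). Over all genes 2 members were called, both lower, and 3 were lower adjusted over the list alone. The antigen presentation call was also lost with knockout replicate 3 alone (adjusted p = 0.105), within a range of 0.00158 to 0.415 over the alternatives. Fragments shared between list members of similar sequence were not counted, which leaves the levels of such members uncertain. The median became -0.0646 after GC correction.

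Of 48 cytosolic ribosomal protein genes, 31 were negative, with a median log2 fold change of -0.0201, and 45 did not pass on their own. The list was called lower only in some set tests, and not by fry (adjusted p = 0.424). Over all genes 3 members were called, all lower, among them RPL18 and RPS15 at 89.3% and 86.7% of wildtype, and 8 were lower adjusted over the list alone. RPL18 and RPS15 lie on chromosome 19. Camera called the cytosolic ribosomal proteins lower (adjusted p = 0.00963; adjusted p = 0.788 with an estimated correlation), and not without wildtype replicate 2 (adjusted p = 0.189) or knockout replicate 2 (adjusted p = 0.404), in a range of 1.4e-05 to 0.897 over the alternatives. With upper quartile scaling it was 0.0363. Ribosomal protein genes have many processed pseudogenes, with which fragments can be shared. The blood group genes were called lower (adjusted p = 0.0247; adjusted p = 0.368 with an estimated correlation) on a list that includes XG and CD99, with B3GALNT1, the globoside synthase, at 78.6% of wildtype as the third called member of 20; 4 were lower adjusted over the list alone. Their call was lost after GC correction (adjusted p = 0.176) and without wildtype replicate 2 (adjusted p = 0.119) or knockout replicate 3 (adjusted p = 0.109), and over the alternatives it ranged from 0.0128 to 0.723.

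**Figure D3:**
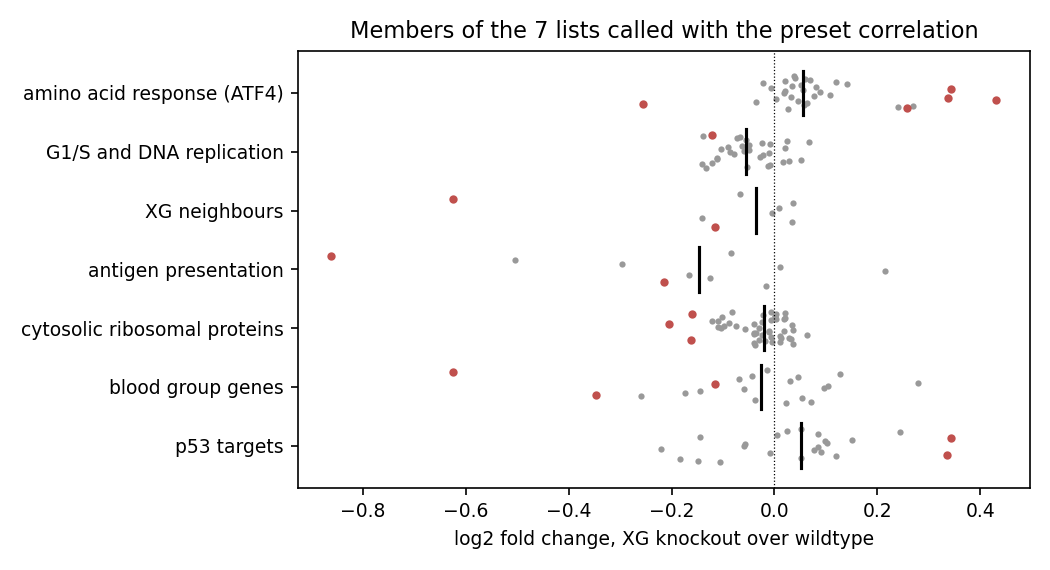
Log2 fold change of XG knockout over wildtype (horizontal axis) for every tested member of the 7 lists called by camera with its preset correlation; red points are genes past an edgeR adjusted p of 0.05, grey points the others, and black lines the list medians. The amino acid response list has 28 of 32 members above 0, and the G1/S list 26 of 32 below 0.

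The remaining 30 of 37 tested lists were not called by camera without GC correction. After GC correction 8 lists were called: the blood group genes were lost, and TGF-beta and BMP signalling (lower, adjusted p = 0.0422; 0.719 with an estimated correlation) and blood cell markers (higher) were gained. In the list of genes activated by EWSR1-FLI1, the fusion oncoprotein of Ewing sarcoma, 1 of 33 members changed: IL1RAP, a coreceptor of interleukin 1, rose to 237 ± 4.65 from 213 ± 6.47 CPM (SD, n = 3). CDKN1A was the called member among 23 tested genes repressed by the fusion. Medians of these lists were 0.00685 and 0.00544. Neuronal genes had 3 of 24 called, all lower: NEFM and NEFL, neurofilament subunits, at log2 fold changes of -0.25 and -0.17, and NGFR, the low-affinity neurotrophin receptor, at -0.23; NGFR lost its call after GC correction (log2 fold change -0.13, SE 0.042). Of 28 HOX genes, HOXA7 and HOXC11 fell, to 46.4% and 79.4% of wildtype, HOXA7 from 1.62 to 0.74 CPM. In the mesenchymal and osteogenic list PDGFRB, a growth factor receptor, rose from 39.1 ± 1.46 to 48.3 ± 2.86 CPM, and ALPL, an alkaline phosphatase of bone, fell from 34.3 ± 1.99 to 26.8 ± 2.07 CPM (SD, n = 3). Single called members elsewhere were SQLE in cholesterol synthesis, ID3 in TGF-beta and BMP signalling, DLC1 among YAP and TEAD targets, UNC5B in axon guidance, JUNB among immediate early genes, FTL in oxidative stress, CTSZ in lysosome and autophagy and XBP1 in the unfolded protein response. Of these XBP1 rose, by 0.13 on the log2 scale, and the others fell. CD99 was the called member of 33 adhesion genes. By edgeR no member passed over all genes in the lists for extracellular matrix, epithelial-mesenchymal transition, interferon, NF-kB, fatty acid synthesis, glycolysis and hypoxia, oxidative phosphorylation, heat shock, MAPK feedback, WNT, NOTCH and histones. Adjusted over the list alone, 3 extracellular matrix genes were higher and 4 lower, and 2 motility genes higher and 2 lower; 1 NF-kB gene was lower, 1 heat shock gene higher and 1 lower, and 1 MAPK feedback gene higher. The smallest adjusted p among these uncalled genes was 0.0505, for CSF1 (log2 fold change -0.51). The median, mean and camera direction differed in sign for several uncalled lists, among them genes activated by EWSR1-FLI1 (median 0.00685, mean -0.00442, lower), those repressed by it (mean -0.0184, higher) and neuronal genes (median 0.00234, mean -0.00544, lower).

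Markers of other cell types were not called as sets without GC correction. After it the 5 tested blood cell markers were called higher by camera (median log2 fold change 0.0928, adjusted p = 0.0179; adjusted p = 0.328 with an estimated correlation), with 1 member past the test. KRT18, an epithelial keratin, rose from 2.03 ± 0.0566 to 3.26 ± 0.231 CPM (SD, n = 3), as 1 of 7 tested epithelial genes, and PDGFRB was 1 of 14 tested fibroblast genes. None of 5 tested blood cell genes passed by edgeR without GC correction. Too few endothelial markers passed the expression filter for a set test, and all mitochondrial genome genes had 0 counts in every library, so their share could not be used as a measure of RNA quality.

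Knockout replicates 1 and 2 differed from the other 4 libraries in a trend with GC content. In the GC-richest of 10 equal groups of genes (61.4% to 74.5%), the median log2 ratio to the wildtype mean was -0.207 in knockout replicate 1, -0.151 in knockout replicate 2 and 0.0275 in knockout replicate 3, and between -0.0136 and 0.0101 in the wildtype libraries. In the group with the lowest GC content (26.7% to 38.3%) it was 0.0714, 0.0613 and 0.00838 in the knockout libraries. Set against the wildtype libraries, which alone supply the spread in that fit, knockout replicate 3 alone gave 128 called genes, 73 higher and 55 lower, of which 72 were also among the 196 with the same sign.

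By chromosome, 7 of 23 chromosome sets were called by camera: 2, 3, 4 and 13 higher, and 9, 16 and 19 lower. Chromosome 19, with a median GC content of 58.4%, had a median log2 fold change of -0.0948 and adjusted p = 2.46e-13. With an estimated correlation 0 chromosomes were called, with adjusted p = 0.301 for chromosome 19. After GC correction 2 were called at the preset correlation, chromosomes 19 (median -0.0374) and 18 (median -0.0454), both lower. With GC correction and an estimated correlation 1 was called, chromosome 19, so the chromosome 18 call was lost.

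**Figure D4:**
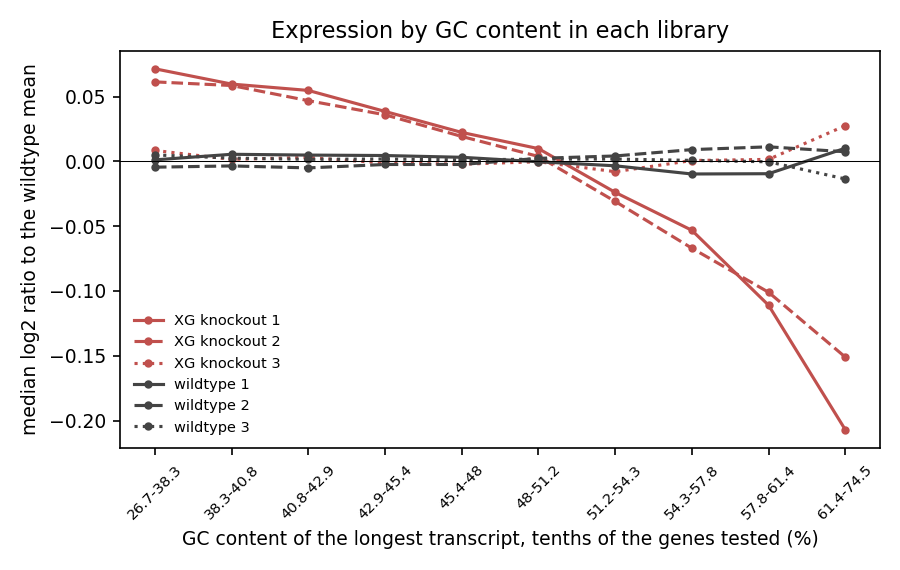
Median log2 ratio of each library to the wildtype mean (vertical axis) in 10 equal groups of the tested genes by GC content of the longest transcript (horizontal axis, percent); each line is a library, grey for wildtype and red for knockout. Knockout replicates 1 and 2 fall to -0.207 and -0.151 in the GC-richest group, and knockout replicate 3 is at 0.0275.

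The authors' deposited table of their own DESeq2 comparison held 199 genes past an adjusted p of 0.05, 46 higher and 153 lower. Its fold changes had the same direction as knockout over wildtype here. Of the 196 genes, 140 were past the threshold in the authors' deposited table with the same sign and 0 with the opposite sign; 43 had no adjusted p there and 13 had one that did not pass. A further 59 genes passed only in the authors' deposited table.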

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

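GC and length corrections, knockout replicate 3 alone, GC correction with each library left out and GC correction with an estimated correlation were chosen after seeing the data. The XG log2 fold change kept its sign and stayed past the threshold in every alternative run, from -0.66 to -0.60. The 196 called genes (64 higher, 132 lower) became 200 to 217 with other scalings, DESeq2 or voom, 647 without a filter (147 and 500), 137 with the stricter filter (85 lower), and 33 at an adjusted p of 0.01 (13 and 20), which follows from the stricter threshold. GC correction gave 339 genes (157 higher) and GC and length correction 377 (161 and 216). Knockout replicate 3 alone gave 128 (55 lower). The replicate number as a block gave 37 genes (12 and 25). Same-numbered libraries did not deviate together (correlations -0.0459, -0.0239 and -0.0512), and none correlated best with its own number. This cannot exclude a pairing, because there are 3 libraries per group and the GC trend of knockout replicates 1 and 2 could hide one. The labels do not say whether the numbers pair the libraries. With each library left out, with or without GC correction, the count ranged from 18 to 1851 (7 to 522 higher, 11 to 1329 lower), and with GC correction from 131 to 393. The 6 genes changed at least 2-fold became 0 with DESeq2 and with the stricter filter, 1 with the block, and 0 to 23 with a library left out. The 7 lists called became 0 with an estimated correlation, with or without GC correction, 2 with rank-based camera, 3 with fry, and 4 to 9 with a library left out. The 7 chromosomes called became 1 without a filter, 2 with GC correction and with GC and length correction, 1 with knockout replicate 3 alone, 0 with an estimated correlation and with fry, 1 with GC correction and an estimated correlation, and 1 to 9 with a library left out. Except where counts fell with fewer libraries or genes, the cause was not tested. The rise to 1851 genes without knockout replicate 3 was not such a fall. Both knockout libraries left in that fit carry the GC trend, and with GC correction it gave 386 genes. No called named gene changed sign. Among uncalled ones, GYG2 (-0.0053) was 0.0045 with upper quartile scaling, 0.017 with GC correction, 0.0068 with length correction, 0.016 with both, 0.0203 with knockout replicate 3 alone and -0.021 to 0.0052 with a library left out; NLGN4X (0.0095) was -0.0082, -0.010 and -0.046 with GC correction, both corrections and knockout replicate 3 alone and -0.025 to 0.038 with a library left out; CD99L2 was -0.035 to 0.084 with a library left out; DHRSX and FASN were 0.081 and 0.0084 with knockout replicate 3 alone.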

Other observations

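Tests on the windows and blocks of neighbouring genes below, and the genes called only after GC correction, were chosen after the results were seen; the tests of GC content on the gene lists, chromosome 19 and the split of calls, and that of a single library, had their bounds set before those tests were run. An explanation was set aside as the whole cause of a list's or chromosome's median where the whole 95% bootstrap interval (1000 draws) left the range set for it, a reading adopted after the values were seen. The draws resampled genes as if they were independent, so these intervals measure neither the spread between libraries nor the correlation between genes.

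With the GC correction, 181 genes passed that had not passed before. Those with the smallest adjusted p among the higher ones were QPRT, an enzyme of NAD synthesis (log2 fold change 0.21, SE 0.0319), HSPG2, the basement membrane proteoglycan perlecan (0.39, SE 0.0612), ITGB2, a leukocyte integrin chain (0.14, SE 0.0224), PRPH, the neuronal intermediate filament peripherin (0.26, SE 0.0443), and JUN, a subunit of the AP-1 factor (0.47, SE 0.0827). Among the lower ones were RBM11 (-0.21, SE 0.038), EWSR1, the 5' partner of the Ewing sarcoma fusion (-0.13, SE 0.026), and VIM, the intermediate filament vimentin (-0.11, SE 0.0227). In the amino acid response (ATF4) list, ATF4 itself (0.11, edgeR adjusted p = 0.00598), PCK2 (0.20) and SLC3A2 (0.089) joined CHAC1, ALDH1L2, SESN2 and DDIT4, for 7 higher and 1 lower. The correction and the genes come from the same libraries, so the added genes are not independent evidence.

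After GC correction 53.7% of calls were lower, inside the range of 40 to 60% set in advance for GC content as the cause of the imbalance. Lower calls did not become fewer: they went from 132 to 182 and higher calls from 64 to 157, while 96 of the 132 lower and 62 of the 64 higher calls were kept. The lower share was 71.8% without knockout replicate 3, which lacks the trend, and 58.2% and 56.1% without knockout replicate 1 or 2. With GC correction it was 58.5%, 47.9% and 58% without knockout replicates 1, 2 and 3. The excess of lower calls was thus largest where both remaining knockout libraries carried the GC trend. GC content is a candidate explanation for the unequal share. Because lower calls rose after correction, the share does not show that GC content produced them. The labels name no batch that could test this further. The corrected median was -0.0237 (95% interval -0.0338 to -0.0158) for the ribosomal protein genes and -0.0409 (-0.0549 to -0.0245) for the replication genes. Both intervals left the ranges set for GC content as the whole cause, within 0.01 and 0.02 of 0. Neither interval lay wholly beyond the other bound set in advance, -0.02 and -0.04. With an estimated correlation neither list was called after GC correction (camera adjusted p = 0.897 and 0.328). A shift that needs another cause was therefore not established.

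The median of the amino acid response genes was 0.0698 after GC correction (95% interval 0.0447 to 0.103), above the 0.02 set for GC content as the cause. That outcome was likely in advance. The list's median GC content was 51.8%, against 48% for all genes tested, and knockout replicates 1 and 2 were lower for GC-rich genes. The correction was thus likely to raise the median, and the test adds no support for the rise. A single library did not explain the higher median, since the lowest of the 3 knockout libraries' medians was 0.0486. The list was not called with an estimated correlation (adjusted p = 0.265, and 0.0665 after GC correction), and culture conditions such as medium depletion or cell density, which raise the same genes, were not recorded in the labels and stay untested.

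Genes of chromosome 19 were lower in the knockout: 37 of 981 tested were called lower and 3 higher, with a median log2 fold change of -0.0948. After GC correction the median was -0.0374 (95% interval -0.0436 to -0.0297; camera adjusted p = 0.00114, and 0.0471 with an estimated correlation), outside the 0.02 set for GC content as the whole cause but short of the -0.05 set for excluding it. Chromosome 19 genes in the lowest of 3 groups by GC content had a median of 0.00626 before correction, which cannot be read against a copy number change because low-GC genes elsewhere stood at 0.0399. After correction the lowest windows of 40 neighbouring genes lay on distal 19q (49869033 to 58605223, 108 genes, median -0.0787) and 18q (46104378 to 80247514, 70 genes, median -0.0597), blocks picked because they were lowest; the higher of these medians was -0.0597, the highest in any knockout library -0.055, and the rest of chromosome 19 was at -0.0325 and of chromosome 18 at -0.0412 (95% interval -0.0513 to -0.0146), so the 18q block lay close to the rest of its chromosome. Window medians of knockout libraries set against different wildtype libraries correlated at a mean of 0.549 over 257 windows, against at most 0.253 in 200 shuffled gene orders, so a copy number difference in part of the knockout cells may underlie the blocks, as a hypothesis that regional regulation would match equally and that DNA was not available here to test.

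The real grouping gave 196 genes and the highest of the 9 other splits of the 6 libraries into 3 and 3 gave 27; 1 of the 10 splits gave as many genes as the real one, itself, and 10 splits are too few for a share under 0.05.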
